A study of Mus musculus with 24 samples.

How the data were processed

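T cells positive for CD45, CD3 and CD8 were sorted from the pancreas or blood of KC and WT B6 mice, and their total RNA was extracted with the Rneasy Plus Micro kit and sequenced, per the labels. The deposited files hold the read count of each gene symbol as the authors counted it, with no normalisation, in 24 libraries with 24421 genes and 5 tallies of reads given to no gene. The labels name TopHat, SAMtools, HTSeq and DESeq for the authors' processing and mm10 as the genome build, with no version, setting or annotation. The files were checked for whole, non-negative counts. Strand use is not stated, so reads of overlapping or antisense genes cannot be told apart. Genes with near-identical copies are uncertain, such as ribosomal protein genes with their pseudogenes, trypsinogens, amylases, elastases, Hspa1a and Hspa1b, and Bcl2a1b.

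Per library, 11.7% to 32.5% of the tallied reads were assigned to genes, 48.6% to 69.7% to no feature and 15.8% to 22.8% were not unique. Pairs of libraries had a median correlation of log2 CPM of 0.831 across genes, which are not independent replicates. Positions of genes were taken from GENCODE annotation of the same build, where 97 of 98 looked-up symbols matched.

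Groups and ages came from the sample labels. Tests were made with edgeR 4.0.16 in R 4.3.3 (filterByExpr with a minimum count of 10, TMM scaling, robust quasi-likelihood F-tests, two-sided), and genes with a Benjamini-Hochberg adjusted p under 0.05 within a comparison were called. The SE of a log2 fold change was its absolute value over the square root of the F statistic, not a spread measured between libraries. Pancreas against blood used the 21 KC libraries with age as a factor. Age trends used the 12 KC pancreas or 9 KC blood libraries with age as a number, in log2 per 10 weeks, and the difference of the trends was the interaction in the 21 KC libraries. Later ages were compared with 4 weeks in a fit of the 12 KC pancreas libraries. KC was compared with WT over 9 and 30 weeks in a fit of 14 pancreas libraries, and at 30 weeks in a fit of 10 blood libraries. The pair of WT libraries of 30 weeks was described by log2 ratios with a prior count of 1 and no test.

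The 37 gene lists held 907 genes of the files and covered T cell states, metabolism, signalling responses and other cells (288 genes). Lists with at least 5 tested genes were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, and their genes were also adjusted over the list alone. For the WT pair, a list's median was placed among 10000 random lists of the same size drawn from 20 bins of mean expression. Shares of counts were compared as log2 of the percent plus 0.001 by exact permutation tests, two-sided. Genes at 0 counts in a group were given a floor of 3 counts over the group.

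Comparisons, tests, lists, a panel of T cell genes and most alternatives were fixed before the data were examined. The genes named were up to 8 per direction with the smallest adjusted p among called genes with an absolute log2 fold change of at least 1 (0.5 per 10 weeks for trends), in no other-cell list and, between tissues, of the same sign in 9 of 9 pairs. Up to 2 genes per list and the panel were added, and other genes were named after their values were seen. Some genes are not reported here by name and are included in the counts and lists.

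Libraries of both tissues that share the number in their title and their age were read as 1 animal, which the labels do not state. In 10 of 10 such pairs, 9 of them KC, both libraries lay on the same side of 1000 CPM of Xist. In the 7 KC pairs of ages with more than 1 pair, deviations from the group means correlated at -0.0604 to 0.0106, and none correlated best with its own number.

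Carry-over sets were derived after the data were seen. Genes with at least 100 CPM in 1 library and at most 5% of that level elsewhere were taken as traces, which gave 90 genes of 14 source libraries with at least 3 genes each, and libraries were grouped by where the traces were detected. No gene of any list entered. Leaving out 1 source moved at most 3 libraries.

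The edgeR fits and camera at the preset correlation were tested on simulated negative binomial counts, and the grouping into carry-over sets on simulated Poisson counts. Other tests and tools were not simulated. For pancreas against blood (10890 genes), 1.49%, 5.97% and 61.5% of genes changed by log2 values of 1, 2 and 4 were recovered. For the trends and their difference, the values of 1, 2 and 4 were slopes in log2 per 10 weeks. Their shares are therefore not comparable with those between tissues. For the age trend the shares were 3.08%, 34.3% and 87.9% in pancreas (9404 genes). They were 3.08%, 26.6% and 87.7% in blood (9603 genes), and 0%, 13.4% and 53.8% for the difference of trends (10893 genes). For KC against WT in pancreas 3.03% was recovered at a log2 fold change of 4 (11762 genes). Against 4 weeks in KC pancreas, 4.55% (9 weeks, 10362 genes), 4.55% (13 weeks, 10339 genes), 1.56% (20 weeks, 10342 genes) and 7.81% (30 weeks, 10301 genes) were recovered at 4. Camera called 0 lists in each of these simulations, and the grouping into carry-over sets placed 24 of 24 simulated libraries. Genes were drawn independently, so the camera result does not cover genes that vary together. The simulated grouping gave every library source genes and left no traces in the other group. In the data 14 libraries were sources and 50.1% of traces were detected in the other set, so the simulated case was clearer.

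Alternatives were RLE scaling, no low-count filter, DESeq2 1.42.0, leaving out each library, title numbers as a block, no age term, paired animals alone, log2 age, the acinar level as a covariate, other-cell genes removed, camera with an estimated correlation, fry, and a prior count of 5 for the WT pair. Added later were set terms, each set alone, leaving out 4 or 13 weeks, Xist as a covariate and removal of Rn45s and Lars2. Variation in sequence and splicing was not analysed here.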

Results

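CD8 T cells kill infected and transformed cells, and their transcripts were measured here in the blood and pancreas of KC mice and wild-type (WT) mice. KC mice are a model of pancreatic cancer in which preinvasive lesions form in the pancreas with age. RNA sequencing covered 24 libraries of sorted T cells: 12 from KC pancreas, 9 from KC blood, 2 from WT pancreas and 1 from WT blood. The KC pancreas libraries came from mice of 4 weeks (n = 3), 9 weeks (n = 2), 13 weeks (n = 3), 20 weeks (n = 2) and 30 weeks (n = 2). The KC blood libraries came from 4 weeks (n = 2), 9 weeks (n = 1), 13 weeks (n = 3), 20 weeks (n = 1) and 30 weeks (n = 2). The WT pancreas libraries were of 9 and 30 weeks and the WT blood library was of 30 weeks. Reads counted in genes ran from 6352070 (Sample_303P8) to 16716200 (Sample_W3B8) per library, with a median of 9602260. Single libraries are named by their titles, which end in P8 for pancreas and B8 for blood. A library detected 10066 to 12949 genes.

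T cell genes were abundant in the data. Cd3e, a subunit of the T cell receptor complex, had 1581850 counts over all libraries and Cd8a, a chain of the CD8 coreceptor, had 323977. Cd4, the coreceptor of helper T cells, had 6635 counts. Tcf7, a transcription factor of naive and memory T cells, had 302672 counts and Tox, a factor tied to exhaustion, had 40520. Several receptors of exhausted T cells were close to the limit of detection. Pdcd1 had 161 counts in 20 libraries, Havcr2 had 31 counts in 9 libraries and the fatty acid transporter Cd36 had 162 counts in 10 libraries, and these 3 were too low to be tested between tissues or for the age trend in KC pancreas. Against WT mice, Havcr2 and Cd36 in pancreas and Pdcd1 and Cd36 in blood were tested with edgeR and did not pass (adjusted p from 0.861). The rRNA precursor Rn45s took 1.86% to 18.2% of the counts of a library and the mitochondrial tRNA ligase gene Lars2 took 0.428% to 4.69%. The biological coefficient of variation was 1.12 to 1.32 over the comparisons, so single genes varied widely between libraries of a group.

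Traces of genes that were high in 1 library were found in other libraries, and they parted the 24 libraries into 2 sets of 12 (carry-over sets). Genes of this kind were detected in 92.3% of cases in libraries of the same set and in 50.1% in libraries of the other set. Their median level was 0.209% of the source in the same set and 0.0153% in the other. Set 1 held KC pancreas of 4 and 13 weeks, Sample_42B8, Sample_43B8 and Sample_131B8, and the 3 WT libraries. Set 2 held KC pancreas of 9, 20 and 30 weeks and the other 6 KC blood libraries. Each comparison is therefore given with its values within sets or with set as a term, where these could be had.

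**Figure D1:**
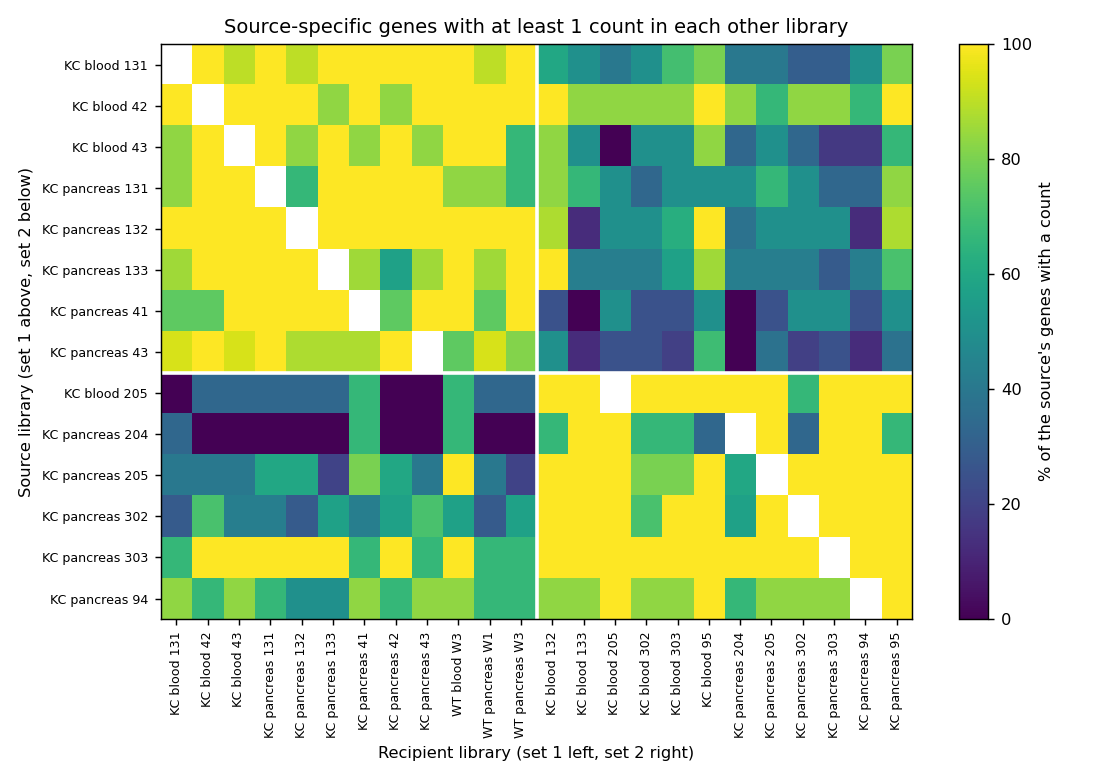
Share (%) of the genes high in 1 source library (14 sources, vertical axis) that had a count in each of the 24 libraries (horizontal axis), with white lines between the carry-over sets. With sets formed without the source in question, the share was higher in the source's own set for 14 of 14 sources.

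The first comparison asks how CD8 T cells in the pancreas of KC mice differ from those in their blood. Immediate early genes, which are transcribed within minutes of receptor signals or stress, rose in the pancreas. They included Fos, Fosb and Egr1, transcription factors induced by such signals, and Dusp1, a phosphatase that ends MAP kinase signalling. Nr4a1, a nuclear receptor induced by T cell receptor signals, Tnfaip3, an inhibitor of NF-kappaB signalling, and Rgs2, a brake on G protein signalling found in resident T cells, also rose. Ppbp, a platelet chemokine, and Alas2, an enzyme of haem synthesis in erythroid cells, fell, and Dmbt1, a secreted protein of the pancreas, rose.

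Of 11059 genes tested with edgeR, 8 were higher and 2 were lower in pancreas at a Benjamini-Hochberg adjusted p under 0.05, and 1089 had an unadjusted p under 0.05. The log2 fold changes (± SE, 12 against 9 libraries) with adjusted p were 3.69 ± 0.60 (0.000771) for Rgs2, 3.15 ± 0.52 (0.000771) for Tnfaip3 and 3.92 ± 0.69 (0.00223) for Egr1. They were 5.26 ± 1.0 (0.00755) for Fosb, 2.92 ± 0.57 (0.00771) for Dusp1 and 5.11 ± 1.03 (0.0135) for Nr4a1. Each of these 6 genes was higher in the pancreas in 9 of 9 pairs of libraries that share a title number. The rule for naming genes asked for this, so it adds no support. Fos rose by 5.50 ± 1.07 (0.00771) and Dmbt1 by 4.63 ± 0.97 (0.0197), each in 8 of 9 pairs. These were named after their values were seen, like Ppbp at -5.14 ± 0.74 (0.000115) and Alas2 at -4.12 ± 0.90 (0.0358), which were lower in 9 of 9 pairs. The count was 6 without Sample_302P8 and 21 without Sample_131B8. Without Sample_302P8, Fosb (adjusted p = 0.102), Dusp1 (0.0785) and Nr4a1 (0.142) did not pass. Nr4a1 also failed without Sample_43P8 (0.0733), Sample_132B8 (0.0608) or Sample_302B8 (0.0513). Alas2 passed without Sample_204P8, Sample_205P8, Sample_133B8, Sample_205B8, Sample_302B8 or Sample_42B8 and failed without any of the other 15 libraries (0.0519 to 0.102). It also failed with title numbers as a block (0.323) and in the paired animals alone (0.151). Dmbt1 failed without Sample_131P8, Sample_303P8, Sample_42P8, Sample_132B8, Sample_302B8, Sample_42B8 or Sample_43B8 (0.0544 to 0.152), with RLE scaling (0.0714) and in the paired animals alone (0.0768). It was also not called with set beside age, without an age term, without the 4-week libraries or in either set alone. Fos and Ppbp passed in 21 of 21 fits with a library left out.

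The carry-over sets were also tested alone with edgeR. Set 1 gave 37 genes, all lower and none among the 10, and set 2 gave 5, of which 4 were among the 10. In set 2 alone, Rgs2 (0.00198), Tnfaip3 (0.0023) and Dusp1 (0.0101) passed, and Egr1 (0.0793), Fosb (0.0617) and Nr4a1 (0.14) did not. In set 1 alone none of the 6 passed, with adjusted p from 0.0951 for Tnfaip3 to 0.229 for Dusp1, and all 6 had positive fold changes. With another scaling (RLE), Dusp1 did not pass (0.0559). Without the 4-week libraries, Egr1 and Fosb (0.0619 each) and Dusp1, Fos and Nr4a1 (0.111 each) did not pass. Nr4a1 also failed with set beside age (0.123), and Fosb (0.0507) and Nr4a1 (0.217) without the 13-week libraries. In build mm10, Rgs2 lies on chromosome 1 from 143999338 to 144004161 and Tnfaip3 on chromosome 10 from 19000910 to 19015657. Egr1 lies on chromosome 18 from 34859823 to 34864984 and Fosb on chromosome 7 from 19302696 to 19310051. Dusp1 lies on chromosome 17 from 26505590 to 26562128 and Nr4a1 on chromosome 15 from 101254269 to 101274795.

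**Figure D2:**
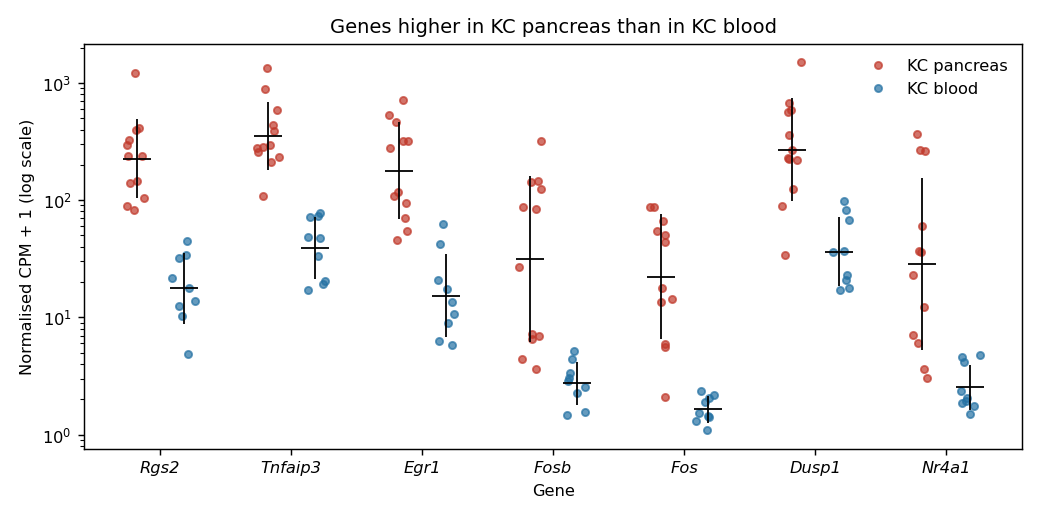
Normalised CPM plus 1 (log axis) of 7 genes that were higher in KC pancreas (red, n = 12) than in KC blood (blue, n = 9); points are libraries and black marks are the mean ± SD of the log10 values. Rgs2 differed by 3.69 and Fosb by 5.26 on the log2 scale.

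Gene lists fixed in advance moved with these genes. The list of immediate early and dissociation stress genes (the immediate early list) also covers stress from taking tissue apart into cells. It rose as a whole: of 34 genes, 30 had positive fold changes and 4 passed over all genes (Dusp1, Egr1, Fos and Fosb). Adjusted over the list alone, 14 rose. Those 14 included the AP-1 factors Junb (3.37) and Atf3 (5.74), the chemokine receptor gene Cxcr4 (1.90) and the heat shock gene Hspa1a (5.32). The tissue residency list, of genes that mark T cells lodged in tissue, also rose, with 20 of 25 genes positive and 2 passing over all genes. Adjusted over the list alone, 6 of its genes rose and 2 fell, and Rgs1 (2.90), P2rx7 (3.15) and Qpct (6.61) were among the former. Cd69 (1.43) and Itgae (1.74), a pair of residency markers, did not pass. The activation list had 22 of 26 genes positive, with Tnfaip3, Bcl2a1b (3.81) and Egr3 (3.34) higher when adjusted over the list alone. The list of inhibitory receptors and exhaustion genes (the inhibitory receptor list) had 16 of 23 genes positive. The 4 that rose over the list alone were Nr4a1, Nr4a2 (4.56), Nr4a3 (3.52) and Irf4 (2.65), while Cd244 (-6.65) fell. These 4 are transcription factors, not inhibitory receptors, and Nr4a1 is also in the tissue residency list. The receptor genes Lag3 (edgeR adjusted p = 0.884), Ctla4 (0.657) and Tigit (0.937) did not pass. The T cell core list and the cytosolic ribosomal protein list, which holds the structural proteins of the ribosome, rose by little at the preset correlation alone (adjusted p = 0.141 and 0.66 with an estimated one), and no member of either passed. The ribosomal median turned to -0.66 in set 1 alone and to -0.14 with set beside age.

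By camera at a preset correlation, the adjusted p was 2.06e-23 for the immediate early list (median log2 fold change 1.28) and 1.6e-07 for tissue residency (1.43). It was 3.36e-06 for activation (0.71) and 8.97e-05 for the list of inhibitory receptors and exhaustion genes (0.93). These 4 lists held with an estimated correlation, at adjusted p = 0.000204, 0.000405, 0.007 and 0.0294. The T cell core list (0.45, adjusted p = 0.00466) and the ribosomal list (0.14, adjusted p = 0.00104) passed at the preset correlation. The ribosomal list failed without Sample_132P8 (0.107), Sample_132B8 (0.183) or Sample_95B8 (0.0613). The median over all genes was -0.12. Of the 32 lists tested, 21 were not called, at adjusted p from 0.0697 to 0.846. With title numbers as a block, the CD4 and regulatory T cell list rose (adjusted p = 0.0331, from 0.0828 without the block; 0.283 with an estimated correlation).

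Within set 1 the immediate early list passed (median 1.5, adjusted p = 0.00124; 0.0935 with an estimated correlation). Tissue residency (1.72, adjusted p = 0.0541), inhibitory receptors (2.17, adjusted p = 0.0805) and activation (0.83, adjusted p = 0.105) did not. Within set 2 the immediate early list (0.79, adjusted p = 3.28e-14) and tissue residency (1.17, adjusted p = 8.42e-06) passed, and each had adjusted p = 0.0293 with an estimated correlation. Inhibitory receptors (1.09, adjusted p = 0.011; 0.196 estimated) and activation (0.74, adjusted p = 0.00177; 0.252 estimated) passed at the preset correlation alone. The ribosomal list fell in set 1 (-0.66, adjusted p = 2.81e-05; 0.707 estimated) and rose in set 2 (0.62, adjusted p = 4.07e-15; 0.297 estimated). The T cell core list had a median of 0.20 with a downward camera direction in set 1 (adjusted p = 0.996), and rose in set 2 (0.50, adjusted p = 0.00558; 0.196 estimated).

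**Figure D3:**
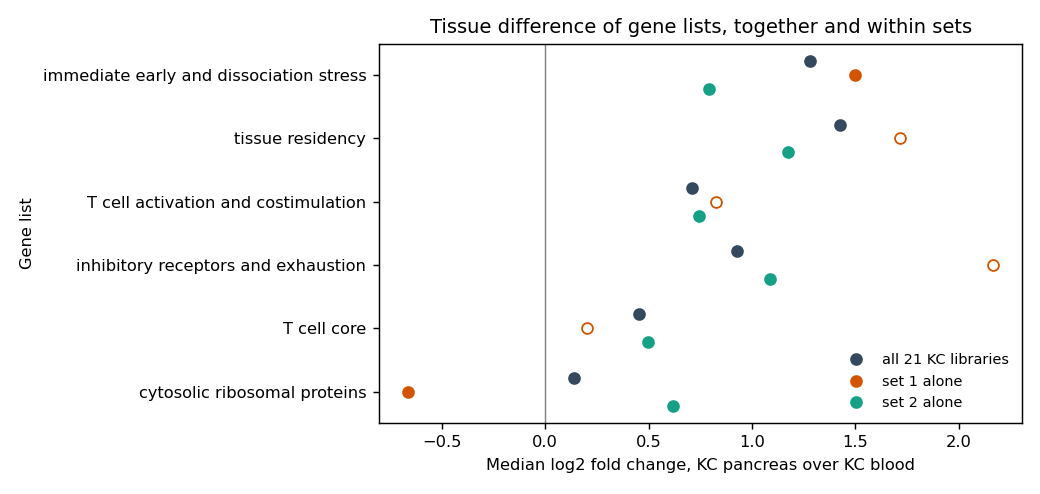
Median log2 fold change of 6 gene lists, KC pancreas over KC blood, in all 21 KC libraries, in carry-over set 1 alone and in set 2 alone; filled points had an adjusted camera p under 0.05 at the preset correlation and open points did not. The list of immediate early and dissociation stress genes had medians of 1.28, 1.5 and 0.79.

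RNA of other cells differed between the tissues as well. Genes of pancreatic acinar cells, which make digestive enzymes, rose in the pancreas as a list, as did fibroblast and macrophage genes, at the preset correlation of camera alone (adjusted p = 0.064, 0.104 and 0.338 with an estimated one). Platelet and erythroid genes fell, which are the transcripts of cells that circulate in blood. Adjusted over the lists alone, 6 of 26 acinar genes rose (Cpb1, Dmbt1, Klk1, Prss2, Reg1 and Tff2), 6 of 8 platelet genes fell (among them Pf4, Tubb1 and Ppbp) and 3 of 6 erythroid genes fell (among them Alas2 and Bpgm). Over all genes, 1 of each list passed. The fibroblast matrix gene Dcn and the monocyte receptor gene Cd14 rose when adjusted over their lists alone.

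The camera adjusted p was 2.65e-24 for the acinar list (26 of 26 genes positive) and 4.99e-10 for the platelet list (median -3.85; 0.000348 estimated). It was 0.000658 for the erythroid list (-2.33; 0.0358 estimated), 0.00132 for the fibroblast list (2.29) and 0.0132 for the macrophage list (1.13). Without Sample_42P8 the fibroblast list did not pass (0.177). The macrophage list failed without Sample_132P8, Sample_302P8, Sample_41P8 or Sample_42P8 or Sample_132B8, Sample_302B8 or Sample_303B8 (adjusted p from 0.0543 to 0.357). With title numbers as a block the macrophage list did not pass (0.0688) and the plasma cell list did (0.0457, from 0.132; 0.153 estimated). Platelet genes took 0.00249% ± 0.00345 of counts (SD, n = 12) in pancreas and 0.0204% ± 0.00993 (n = 9) in blood (two-sided exact permutation test, adjusted p = 0.00047 over 23 measures). Erythroid genes took 0.00432% ± 0.00444 in pancreas and 0.0236% ± 0.0172 in blood (n = 12 and 9, exact permutation adjusted p = 0.00669). Acinar genes took 0.207% ± 0.421 in pancreas and 0.00398% ± 0.00538 in blood and did not pass (n = 12 and 9, exact permutation p = 0.0368, adjusted p = 0.234). Within sets, over 6 exact permutation tests, the platelet share differed in both (adjusted p = 0.0238 in each), as did the erythroid share (0.0238 and 0.0468). The acinar share differed in set 1 (0.0468) and not in set 2 (0.0952).

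Genes of T cell function that were chosen in advance did not pass between the tissues with edgeR, and DESeq2 called Ifng (3.82, adjusted p = 0.0178). Tcf7 was 0.95 ± 0.34 (adjusted p = 0.306) on the log2 scale, Tox 1.42 (0.408), the cytokine gene Ifng 3.60 (0.322) and the checkpoint receptor gene Ctla4 1.86 (0.657). The cytotoxic granule gene Gzmb was -1.81 (0.586), the fatty acid oxidation genes Acadvl and Cpt1a were 2.31 (0.507) and -0.81 (0.831; 0.51 without Sample_42B8), and Cd8a was 0.05 (0.986). The sign of Ctla4 turned without an age term (-0.33) and in set 1 alone (-1.78). The edgeR test in simulated data recovered 61.5% of genes changed by 4 on the log2 scale and 5.97% of those changed by 2. The cytotoxic effector list had a median of -0.08 with an upward camera direction and was not called (adjusted p = 0.731). The fatty acid oxidation list was also not called (0.45, adjusted p = 0.477).

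The same contrast was seen once in a WT mouse, with 1 library per tissue at 30 weeks, so it has no replicate check. All 10 genes called in KC mice had the same sign there. The log2 fold changes were 2.05 for Rgs2, 1.90 for Tnfaip3, 0.72 for Egr1, 2.07 for Dusp1 and 3.50 for Nr4a1. Fos had 480 counts in pancreas and 11 in blood, and Fosb had 21 and 20. The immediate early list as a whole had a median of 0.07, at percentile 15.3 among 10000 random lists of like size and expression. The acinar list lay at percentile 100, cytotoxic effectors at 98.1 (median 0.60), B cell genes at 0.12, platelet genes at 0.06 and erythroid genes at 0.04.

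The next comparison asks how CD8 T cells of the KC pancreas change as mice age. The genes that fell with age were mostly those of acinar cells, with digestive enzymes such as the carboxypeptidase Cpa1. Of 26 acinar genes, 15 fell, 0 rose and 11 did not pass over all genes, and 21 fell when adjusted over the list alone. The fibroblast matrix genes Col3a1 and Bgn fell too, among 4 of 8 over the list alone. Outside the lists, Agrn and Nid1, a pair of basement membrane components, Csf2rb2, a cytokine receptor subunit, Slc25a30, a mitochondrial carrier, Ndufaf6, an assembly factor of respiratory complex I, and the small nucleolar RNA Snora61 fell. Trip13, a mitotic checkpoint ATPase, Prkce, a protein kinase C, Igsf6, an immunoglobulin family receptor, and the uncharacterised gene Gm527 rose.

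Of 9555 genes tested with edgeR, 4 rose and 24 fell, and 855 had an unadjusted p under 0.05. Slopes per 10 weeks (± SE, n = 12 libraries, adjusted p) were 4.19 ± 0.68 (0.0110) for Trip13, 4.31 ± 0.74 (0.0110) for Gm527, 2.70 ± 0.58 (0.0377) for Igsf6 and 2.83 ± 0.62 (0.0492) for Prkce. They were -5.96 ± 1.0 (0.0110) for Slc25a30, -6.33 ± 1.10 (0.0110) for Csf2rb2, -6.08 ± 1.13 (0.0119) for Agrn and -6.89 ± 1.28 (0.0119) for Nid1. These slopes are estimates of the fit with no floor of counts, so they are not measured folds. Against blood, Nid1 was higher in pancreas in 4 and lower in 1 of 9 pairs, and Agrn higher in 2 and lower in 4. The other pairs had equal levels, as at 0 counts in both libraries. Each rise was lost without 1 library of 30 weeks. Without Sample_303P8, Trip13 (adjusted p = 0.372), Prkce (0.959) and Igsf6 (slope -0.22, 0.998) did not pass, and without Sample_302P8, Gm527 (0.257) did not. Without Sample_41P8, Slc25a30 (0.0763) failed, and without Sample_43P8, Nid1 (0.184) and Ndufaf6 (0.731) failed. Igsf6 also failed without Sample_131P8, Sample_204P8, Sample_41P8, Sample_42P8, Sample_43P8, Sample_94P8 or Sample_95P8 (0.0511 to 0.11), and Prkce without Sample_131P8, Sample_132P8, Sample_133P8, Sample_204P8, Sample_205P8, Sample_41P8, Sample_42P8, Sample_43P8 or Sample_95P8 (0.0545 to 0.137). Ndufaf6 also failed without Sample_204P8, Sample_205P8 or Sample_302P8 (0.0624 to 0.0844), and Snora61 without Sample_204P8, Sample_205P8, Sample_302P8 or Sample_303P8 (0.051 to 0.0621). Cpa1 failed without Sample_42P8 (0.101), Col3a1 without the same 4 libraries as Snora61 (0.051 to 0.0612) and Bgn without Sample_205P8, Sample_302P8 or Sample_303P8 (0.0624 to 0.0753). The count was 16 without Sample_204P8, 18 without Sample_205P8, 17 without Sample_41P8 and 10 without Sample_42P8. Agrn passed in 9 of 9 and Csf2rb2 in 12 of 12 fits with a library left out that tested them. Slc25a30 lies on chromosome 14 from 75760117 to 75787037 and Agrn on chromosome 4 from 156165290 to 156197488. By camera, the acinar list (adjusted p = 2.13e-35; 0.334 with an estimated correlation) and the fibroblast list (0.00128; 0.637 estimated, and 0.738 at the preset correlation without Sample_42P8) fell. The ribosomal list rose, with 50 of 56 genes positive (0.11, adjusted p = 0.0402; 0.921 estimated), turned to -0.46 without the 4-week libraries (adjusted p = 0.00355), and failed without Sample_204P8, Sample_205P8, Sample_41P8, Sample_42P8, Sample_43P8, Sample_94P8 or Sample_95P8 (0.0544 to 0.671).

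Within carry-over sets no single gene of this trend passed, in fits of 6 libraries each. With set as a covariate, edgeR called 0 genes (624 at an unadjusted p under 0.05). It called 0 in set 1 alone (1246), 0 in set 2 alone (275) and 0 without the 4-week libraries (541). It also called 0 with Xist as a covariate (933). The acinar list fell at the preset correlation with set as a covariate (median -3.89 per 10 weeks, adjusted p = 0.0102; 0.884 with an estimated correlation) and in set 1 alone (-5.22, adjusted p = 8.69e-18; 0.411 estimated). Xist, transcribed from the inactive X chromosome, was over 1000 CPM in 3 of 3 KC pancreas libraries of 4 weeks and in 2 of 9 later ones. DESeq2 on the pooled data called 735 genes and the fit without a low-count filter 686.

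Each later age was then set against 4 weeks. As a list, the acinar genes were lower at each later age by camera at the preset correlation. With an estimated correlation the list held at 9 weeks alone, and at 13 weeks Ctrb1 was the only acinar gene to pass over all genes. Ctrb1, a chymotrypsinogen on chromosome 8 from 111686519 to 111691010, had a mean of 2022 normalised CPM at 4 weeks and 0 counts at 9, 20 and 30 weeks. With a floor of 3 counts over the group, it was at least 17163-fold lower at 9 weeks, at least 9665-fold at 20 weeks and at least 9957-fold at 30 weeks. These limits fell to 4642 without Sample_95P8, 5492 without Sample_204P8, 4173 without Sample_205P8, 4343 without Sample_302P8 and 5613 without Sample_303P8. At 13 weeks it had 26.2 to 38.2 CPM, near the 27.5 to 28.0 of set 1 blood, so its fall of 36.4-fold is at most a lower bound. Floors and intervals cover counting error only. At 4 weeks acinar genes took 0.233% (95% Wilson interval 0.231 to 0.236), 1.42% (1.41 to 1.43) and 0.619% (0.614 to 0.624) of counts. At 13 weeks they took 0.126% (0.124 to 0.129), 0.0564% (0.0548 to 0.0581) and 0.0148% (0.014 to 0.0156), of which Dmbt1 alone held 1041 CPM in Sample_131P8 and Prss2 416 CPM in Sample_132P8. KC pancreas of 9, 20 and 30 weeks lay in set 2 and of 4 weeks in set 1, so for these ages the set and the age cannot be told apart.

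**Figure D4:**
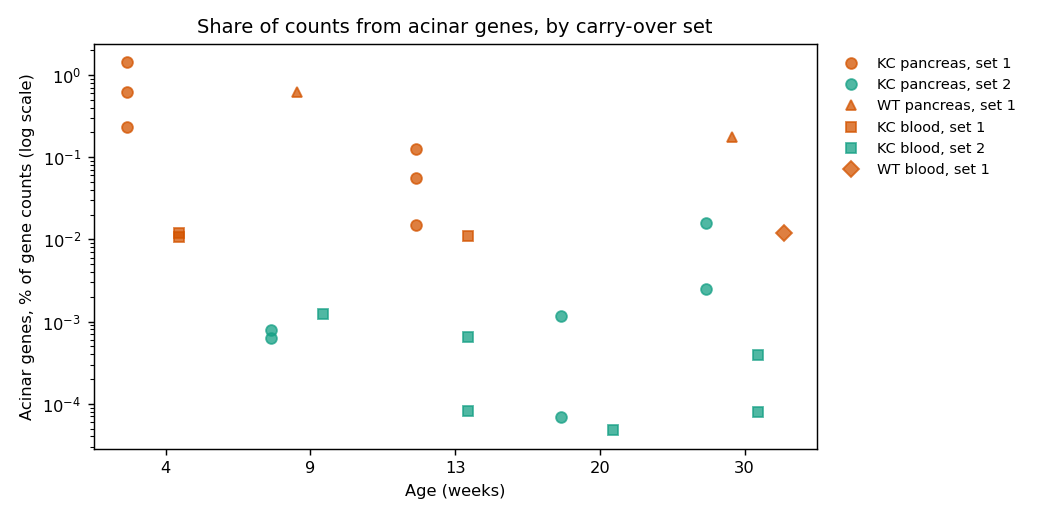
Acinar genes as % of gene counts (log axis) per library against age in weeks (ages evenly spaced); orange marks set 1 and green set 2, with circles for KC pancreas, squares for KC blood, triangles for WT pancreas and a diamond for WT blood. The 4-week KC pancreas libraries held 0.233% to 1.42%.

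At 9 weeks, edgeR called 0 genes higher and 7 lower than at 4 weeks, all 7 of them acinar genes, and 689 had an unadjusted p under 0.05. By camera the acinar list fell (adjusted p = 6.68e-67; 0.0408 with an estimated correlation), and 27 of 29 genes fell when adjusted over the list alone. At the preset correlation, lists of fibroblast genes (adjusted p = 2.41e-08), macrophage genes (1.43e-05), proliferation genes (0.00157), unconventional T cell genes (0.00157), inhibitory receptors (0.0139), ductal genes (0.0145), immediate early genes (0.0274) and NK genes (0.0448) fell. With the acinar level as a covariate the proliferation median turned to 1.32 and the ductal one to 9.84. Mki67 and Tpx2, genes of dividing cells, and Il17re, Il23r and Maf, genes of T cells that make interleukin-17, fell when adjusted over their lists alone. The type I interferon list (0.00157), of antiviral genes, and the B cell list (0.0109) rose. None of these lists other than the acinar one held with an estimated correlation (adjusted p from 0.111 to 0.218). Without Sample_42P8, Sample_94P8 or Sample_95P8 the count was 1, and without Sample_131P8, Sample_132P8, Sample_133P8, Sample_204P8, Sample_205P8, Sample_302P8 or Sample_303P8 it was 12 to 18. Without Sample_95P8 the lists of B cell (0.0813), NK (0.293), immediate early (0.244), inhibitory receptor (0.172), ductal (0.172), proliferation (0.0642) and unconventional T cell genes (0.076) did not pass. Without Sample_94P8 the interferon list did not (0.406), and without Sample_42P8 the lists of proliferation (0.132) and unconventional T cell genes (0.209) did not. Other libraries left out also ended the calls of the B cell, NK, immediate early, inhibitory receptor and ductal lists, at adjusted p from 0.0513 to 0.183.

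At 13 weeks, the 1 age in the same set as 4 weeks, ribosomal protein genes rose as a list at the preset correlation alone (adjusted p = 0.262 with an estimated one). Of 56 ribosomal protein genes, 9 rose over all genes and 53 when adjusted over the list alone, such as Rps24 and Rps28. Eef1a1 (chromosome 9, 78478449 to 78489151), the elongation factor that brings tRNA to the ribosome, and Cd3e rose as well. Interferon-induced genes rose in 7 of 28 cases over the list alone, among them Ifit1 and Ifit3. Ctrb1 fell, and 20 of 29 acinar genes fell over the list alone.

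With edgeR, 25 genes were higher and 1 was lower, and 2122 had an unadjusted p under 0.05. Log2 fold changes (± SE, n = 3 against 3, adjusted p) were 2.16 ± 0.37 (0.00343) for Eef1a1, 2.68 ± 0.48 (0.00662) for Rps24, 3.30 ± 0.60 (0.00662) for Rps28, 2.06 ± 0.42 (0.0168) for Cd3e and -5.21 ± 0.85 (0.00343) for Ctrb1. Fcho1, an endocytosis gene, rose by 7.32 ± 1.44 (0.0152) and did not pass without Sample_132P8 (0.331). The count was 0 without Sample_42P8 or Sample_43P8, 1 without Sample_41P8, and 84 to 143 without Sample_131P8, Sample_133P8, Sample_204P8, Sample_205P8, Sample_302P8 or Sample_303P8. In the 6 libraries of set 1 alone edgeR called 0 genes (1246 at an unadjusted p under 0.05), with Eef1a1 at adjusted p = 0.0562. RLE scaling gave 77 genes and DESeq2 728, and RLE moved the median of all genes from -0.22 to 0.22. Ribosomal protein genes took 8.69%, 12.7% and 8.09% of counts in Sample_131P8, Sample_132P8 and Sample_133P8, and 4.61%, 6.38% and 3.87% in Sample_41P8, Sample_42P8 and Sample_43P8. TMM factors over all libraries were 0.827, 0.474 and 0.565 in the former and 1.17, 1.21 and 0.890 in the latter. A factor under 1 raises the scaled level of every gene of a library, so these folds depend on the scaling. By camera the ribosomal list rose (median 1.81, adjusted p = 1.64e-30) and failed with an estimated correlation (0.262). The fit of set 1 alone holds the same libraries of 4 and 13 weeks, so it repeats this contrast (1.89, adjusted p = 1.25e-25, and 0.411 estimated). The type I interferon list (2.19, adjusted p = 1.16e-06; 0.138 estimated) and the oxidative phosphorylation list (1.10, adjusted p = 0.000594; 0.117 estimated) rose. The acinar list (adjusted p = 1.32e-14) and the fibroblast list (0.00058) fell, both at 0.262 with an estimated correlation.

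At 20 weeks, 1 gene was higher and 8 were lower than at 4 weeks (edgeR), and at 30 weeks 1 was higher and 6 were lower. All of the lower genes belonged to the acinar list. The higher gene at 20 weeks was Zfp239, a zinc finger gene (adjusted p = 0.0375; 0.692 without Sample_204P8 and 0.0819 to 0.238 without Sample_41P8, Sample_42P8 or Sample_43P8). At 30 weeks it was Gm527 (0.0485; 0.747 without Sample_302P8 and 0.0551 to 0.369 without Sample_41P8, Sample_42P8, Sample_43P8 or Sample_95P8). With RLE scaling the calls were 2 higher and 7 lower at 20 weeks and 0 higher and 3 lower at 30 weeks. By camera the acinar list fell at 20 weeks (adjusted p = 1.24e-45; 0.104 with an estimated correlation) and at 30 weeks (1.73e-44; 0.125). The type I interferon list rose at 20 weeks, with 26 of 28 genes positive (2.33, adjusted p = 4.09e-08; 0.104 estimated; 0.0504 at the preset correlation without Sample_205P8). The fibroblast list fell at 20 weeks (7.05e-07; 0.134 estimated) and at 30 weeks (5.02e-05; 0.51). Unconventional T cell genes (0.00251; 0.104), macrophage genes (0.00567; 0.43) and plasma cell genes (0.0469; 0.261) fell at 20 weeks, and proliferation genes (0.0339; 0.518) fell at 30 weeks. The ribosomal list rose at 20 weeks (0.91, adjusted p = 1.86e-09; 0.43) and at 30 weeks (0.38, adjusted p = 0.0339; 0.855). Proliferation genes did not pass without Sample_42P8 (0.842), Sample_302P8 (0.165), Sample_303P8 (0.0577) or Sample_95P8 (0.0613), unconventional T cell genes failed without Sample_42P8 (0.12), and macrophage genes failed without Sample_205P8 (0.0592). Plasma cell genes failed without any of 7 libraries, up to 0.238 without Sample_43P8, and the ribosomal list at 30 weeks without Sample_303P8 (0.245), Sample_41P8 (0.244) or Sample_43P8 (0.0738). Without Sample_42P8 the count was 1 at each age. It was 2 without Sample_204P8 and 5 without Sample_43P8 at 20 weeks, and 3 without Sample_303P8 and 4 without Sample_302P8 or Sample_43P8 at 30 weeks. It was 14 to 30 at 20 weeks without Sample_131P8, Sample_132P8, Sample_133P8, Sample_302P8 or Sample_303P8 and 14 to 27 at 30 weeks without Sample_131P8, Sample_132P8, Sample_133P8, Sample_204P8 or Sample_205P8.

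In KC blood, the question was whether circulating CD8 T cells change over the same ages. Genes of the ribosome and of oxidative phosphorylation, the mitochondrial chain that makes ATP, fell as lists at the preset correlation alone (adjusted p = 0.516 and 0.365 with an estimated one), and no single gene passed with edgeR. With set as a covariate, the slope of the ribosomal list was 0.0045 and that of the acinar list 0.22. All 56 ribosomal genes and 63 of 75 oxidative phosphorylation genes had negative slopes. Acinar genes and T cell core genes fell as lists too, at the preset correlation alone (adjusted p = 0.365 and 0.457 with an estimated one). With edgeR, 0 of 9933 genes were called and 870 had an unadjusted p under 0.05 (n = 9 libraries). DESeq2 called 412, the fit without a low-count filter 102 and the fit on log2 age 16. Without Sample_302B8 or Sample_303B8 the count was 12 and without Sample_42B8 it was 3. The adjusted camera p was 2e-13 for the ribosomal list (median -0.76 per 10 weeks), 1.7e-06 for oxidative phosphorylation (-0.86), 8.45e-13 for acinar genes and 0.0361 for the T cell core (-0.54). The T cell core list failed without Sample_302B8 (0.146), Sample_303B8 (0.24) or Sample_42B8 (0.139).

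The difference between the age trends of pancreas and blood was tested by an interaction term. Slc25a30, Dusp18, a phosphatase, Gpr182, an endothelial chemokine receptor, Mavs, an adaptor of RNA sensing, and Rad51c, a DNA repair gene, were among 6 genes that had lower slopes in pancreas. Ribosomal, immediate early and oxidative phosphorylation genes had higher slopes in pancreas as lists at the preset correlation, and each had adjusted p = 0.521 with an estimated one. With edgeR, 0 genes were higher and 6 lower of 11059, and 921 had an unadjusted p under 0.05. The differences per 10 weeks (± SE, 12 and 9 libraries) were -6.50 ± 1.21 for Slc25a30, -8.20 ± 1.61 for Dusp18, -9.84 ± 1.91 for Gpr182 and -4.17 ± 0.85 for Mavs (each at adjusted p = 0.0407), and -5.35 ± 1.11 for Rad51c (0.0412). These are estimates of the fit with no floor of counts, so they are not measured folds. Gpr182 was higher in pancreas in 2 and lower in 3 of 9 pairs, and Dusp18 higher in 3 and lower in 3. The other pairs had equal levels, as at 0 counts in both libraries. With title numbers as a block, or with RLE scaling or log2 age, 0 genes were called (499 at an unadjusted p under 0.05 with the block), and with set as a covariate 1. The count was 0 without Sample_131P8, Sample_204P8, Sample_205P8, Sample_303P8 or Sample_95P8 or Sample_132B8, Sample_302B8, Sample_43B8 or Sample_95B8, 1 without Sample_43P8 or Sample_133B8, 2 without Sample_42B8 and 13 without Sample_302P8. Slc25a30 also failed without Sample_41P8 (0.14), and Mavs (0.881) and Rad51c (0.0952) without Sample_303B8. DESeq2 called 343. The camera adjusted p was 1.41e-18 for ribosomal (median 0.89; 4.17e-15 with the block), 0.0451 for immediate early (0.37; 0.0932 with the block) and 0.0451 for oxidative phosphorylation genes (0.52; 0.373 with the block). The immediate early and oxidative phosphorylation lists each failed without Sample_204P8, Sample_41P8, Sample_94P8, Sample_95P8, Sample_131B8, Sample_302B8 or Sample_42B8. The former also failed without Sample_132P8 or Sample_302P8 and the latter without Sample_205P8 or Sample_43P8, with adjusted p up to 0.444 and 0.435.

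The last comparisons set KC against WT mice. In the pancreas, mice of 9 and 30 weeks were compared, and acinar genes were lower in KC libraries, with 23 of 32 passing over all genes and 30 when adjusted over the list alone. Malat1 (chromosome 19, 5795690 to 5802672), a nuclear long noncoding RNA, was higher in KC libraries, and the rRNA precursor Rn45s and Lars2 were lower. Reads in no annotated feature took 51.2% and 54.5% of reads in the WT libraries and 59.5% to 69.7% in the 4 KC libraries. Nat14, an acetyltransferase, and Dyrk4, a kinase, were also lower. At the preset correlation alone (adjusted p = 0.526 and 0.646 with an estimated one), immediate early genes were higher as a list and fibroblast genes were lower. With the acinar level as a covariate the immediate early median turned to -0.13. Of the fibroblast genes, Acta2 and Fn1 were higher and Col1a2, Col3a1, Gsn and Sparc lower over the list alone.

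With edgeR, 1 gene was higher and 27 were lower (4 KC against 2 WT libraries, in a fit of all 14 pancreas libraries), and 717 had an unadjusted p under 0.05. Log2 fold changes (± SE, adjusted p) were 2.49 ± 0.25 (4.85e-19) for Malat1, -1.64 ± 0.15 (3.48e-24) for Rn45s, -1.43 ± 0.23 (1.46e-06) for Lars2, -9.74 ± 2.26 (0.00872) for Nat14 and -8.44 ± 2.04 (0.0165) for Dyrk4. In the KC libraries Rn45s took 3.12% and 6.54% of counts at 9 weeks and 12.1% and 2.63% at 30 weeks. Lars2 took 0.796% and 1.84% at 9 weeks and 3.58% and 0.728% at 30 weeks. The SE and p of Rn45s and Lars2 come from the fit and do not measure that spread. DESeq2 did not call Malat1 (0.186), Rn45s (0.518) or Lars2 (0.58) and called 175 genes in all, 123 higher and 52 lower. Lars2 also failed with RLE (0.445) and Rn45s without the low-count filter (0.905). With the acinar level as a covariate, 4 genes were called and Malat1 was not. Without Sample_94P8 or Sample_95P8, Rn45s, Lars2, Nat14 and Dyrk4 did not pass (adjusted p from 0.42 to 1), and the count was 13 and 8. It was 15 without Sample_302P8 and 17 without Sample_303P8. Nat14 and Dyrk4 also failed without Sample_302P8 (0.239 and 0.452) or Sample_303P8 (0.499 and 0.349), and Dyrk4 without Sample_132P8 (0.286). The camera adjusted p was 5.33e-65 for acinar (0.0639 with an estimated correlation), 0.0334 for immediate early (median 1.03; 0.428 without Sample_302P8 and 0.0588 without Sample_95P8) and 0.0389 for fibroblast genes (0.28 without Sample_302P8, 0.371 without Sample_95P8, 0.0681 without Sample_303P8, 0.0548 without Sample_131P8 and 0.056 without Sample_132P8). Both WT libraries lay in set 1 and the 4 KC libraries in set 2, so set and genotype cannot be told apart. The median over all genes was 0.41.

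In blood, the 2 KC libraries of 30 weeks were compared with the WT library of that age, in a fit of all 10 blood libraries. Genotype cannot be told apart from that 1 library, so the differences below describe it alone. At the preset correlation it held more of the platelet, erythroid, B cell, acinar and glycolysis lists and less of the cytotoxic effector and neutrophil lists than the KC libraries. With an estimated correlation all 7 failed (adjusted p = 0.609 for acinar and 0.567 for the others), and the acinar median (KC over WT) turned to 1.34 with set as a covariate. With edgeR, 0 of 12496 genes were called and 354 had an unadjusted p under 0.05, and DESeq2 called 10. Without Sample_131B8 the count was 1, without Sample_132B8 it was 2, and with set as a covariate it was 5. In simulated data of this design edgeR recovered 0% of genes at any of the 3 fold sizes. The camera adjusted p was 8.32e-09 for acinar, 5.21e-05 for platelet, 0.0051 for B cell, 0.0304 for cytotoxic (median 1.63) and for erythroid, and 0.0418 for glycolysis (-1.0) and for neutrophil genes. Without Sample_302B8, the B cell (0.152), cytotoxic (0.152), erythroid (0.231), glycolysis (0.314) and neutrophil lists (0.452) did not pass. Other libraries left out ended the cytotoxic, erythroid, glycolysis and neutrophil calls at adjusted p from 0.05 to 0.0992. RLE moved the median of all genes by 0.20. The lone WT library was assumed to vary like the KC libraries. It lay in set 1 and the KC libraries of 30 weeks in set 2.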

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

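Tests of acinar RNA, tissue handling and carried-over reads, the test of sets for 9, 20 and 30 weeks, and the swaps within pairs were chosen only after the result was seen.

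In KC blood, 6 of 31 measures had a library far from the other 8. The cutoff is set for chance to do this in about 1 in 20 groups of normal values, and the rate for CPM of variable genes was not measured. Ctla4, a checkpoint receptor gene, had 848 CPM in Sample_131B8 and at most 10.8 elsewhere. Gzmb, a granule protease gene of killer cells, had 543 in Sample_205B8 (next 194), and Cpt1a, the gate enzyme of fatty acid oxidation, had 1166 in Sample_42B8 (next 178). Alas2, of haem synthesis, had 224 in Sample_131B8 (next 60.4), and the inhibitory receptor gene Lag3 had 3.40 in Sample_95B8 (next 0.895). Gene counts were 16.4 M reads in Sample_132B8 (next 11.2 M).

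By the interaction test, 6 genes and 3 lists had age trends that differed between pancreas and blood, and these calls depended on the settings. With title numbers as a block, edgeR called 0 genes (499 at an unadjusted p under 0.05; DESeq2 without the block 343) and 2 lists failed (0.0932 and 0.373). With an estimated correlation each list had adjusted p = 0.521. Per 10 weeks the differences of 5 of these genes were -6.50 for Slc25a30, -8.20 for Dusp18, -9.84 for Gpr182, -4.17 for Mavs and -5.35 for Rad51c. They are estimates of the fit with no floor of counts. The list medians were 0.37 for immediate early genes, 0.52 for oxidative phosphorylation and 0.89 for ribosomal proteins. Other orders of the samples gave as many called genes in 13 of 100 cases, the real one included (6 real, highest other 48), so chance cannot be excluded. The 48 calls may come from a structure of the samples, which was not tested.

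Immediate early genes such as Fos, Egr1 and Dusp1 were higher in KC pancreas than in KC blood, as was the list that holds them together with dissociation stress genes. The tables argue against the carry-over set as the whole cause, since the list passed at the preset correlation in set 1 alone (adjusted p = 0.00124; 0.0935 with an estimated correlation) and set 2 alone (3.28e-14; 0.0293). None of the 6 named genes passed in set 1 alone, where their log2 fold changes were 2.48 to 5.22 with SE of 1.16 to 1.84 (2.92 to 5.26 with SE of 0.52 to 1.03 in all libraries). The tables also argue against acinar RNA as the whole cause, since the list also passed in set 2 (3.28e-14; 0.0293 with an estimated correlation), where Ctrb1 had 0 counts. Acinar RNA was low there but not absent, with mean shares of 0.0035% of counts in pancreas and 0.00041% in blood. Handling of the tissue before sorting may raise these genes and stays open, as the WT pair, at percentile 15.3, came through the same 2 tissues only once. Signals in the tissue stay open and untested.

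Acinar genes were abundant at 4 weeks and in the WT pancreas libraries, and present at a low level in the other libraries of set 1. Reads carried over between libraries are a candidate source in blood, since Ctrb1 was alike in the 4 blood libraries of set 1 (highest over lowest 1.02), and at 13 weeks, where the median of 21 acinar genes lay at 0.926 to 1.14 times the highest of that blood. Single genes were above it, with Dmbt1 at 83.2 times in Sample_131P8 and Prss2 at 104 times in Sample_132P8. The tables argue against carried-over reads as the whole source at 4 weeks, where the lowest Ctrb1 level was 23.8 times the highest in that blood. At 4 weeks RNA of acinar cells that passed the CD45, CD3 and CD8 sort may be the source. Acinar genes kept their order between the 3 KC libraries of 4 weeks and the 2 WT pancreas libraries (median rho across genes 0.908). Any source of acinar RNA would keep this order, so it does not tell sources apart. KC pancreas of 4 and 13 weeks lay in set 1, so the set did not differ between these ages. The fit of set 1 alone repeats that contrast (adjusted camera p = 8.69e-18 at the preset correlation, and 0.411 with an estimated one). For 9, 20 and 30 weeks, 0 KC pancreas libraries lay in set 1, so there age and set cannot be told apart. A change of the acinar tissue with age stays open and untested.

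Ribosomal protein genes were higher at 13 than at 4 weeks in KC pancreas. All KC pancreas libraries of both ages lay in set 1, so the carry-over set did not differ between them. The fit of set 1 alone repeats the same contrast and adds no support (median 1.89, adjusted camera p = 1.25e-25 at the preset correlation). With an estimated correlation the list did not pass (0.262, and 0.411 in set 1 alone). In a test of transcript length, the list's median of 1.81 lay at percentile 99.94 of 10000 lists matched on length and expression. Those lists had a median of 1.33 and a highest value of 1.89. Their genes were drawn independently, so the percentile does not measure variation between libraries and cannot decide on transcript length. Across genes, transcript length and log2 fold change had a Spearman rho of -0.0342. The lists were matched on expression as well, so their shift does not tell length from abundance. It leaves a bias toward abundant or short transcripts as a possible explanation for part of the rise. Age, the scaling of the libraries, and the sex of the mice that Xist tracks, stay open.

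Other splits of the samples were tested for 4 more counts. For pancreas against blood, 1 of 100 splits, the real one, gave 10 genes (highest other 5). With swaps within pairs 2 of 100 gave at least 10 (highest other 15), so chance is unlikely but not excluded. For the age trend in pancreas chance cannot be excluded, as 11 of 100 orders gave at least the 28 genes and the highest other gave 151. In blood the real count was 0, so that 100 of 100 orders gave as many by construction, which says nothing of chance; the highest other gave 327. Orders calling 151 and 327 genes may come from a structure of the samples, which was not tested. For 13 against 4 weeks 10 splits were too few for a share under 0.05; the real one gave 26 genes and the highest other 2, and 1 of 10 was as large.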

How the results depend on the processing

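Set terms, fits of 1 set, fits without 4 or 13 weeks, Xist as a covariate and the removal of Rn45s and Lars2 were chosen after seeing the data. Counts of called genes depended on the tool and the scaling, and so did the balance of higher and lower genes with DESeq2. For each result given below that did not hold the cause was not tested, except that fits of fewer libraries have less power by construction. Of 3731 alternatives for single genes, 3178 kept direction and side of the threshold, 288 lost the call, 260 had the other sign and were called in neither fit, 4 gained the call and 1 called value turned. Of the alternatives for lists other than left-out libraries, 180 lost the call, 10 turned and the others kept both, and with left-out libraries 665 kept both and 115 lost it. With 6352070 to 16716200 counts per library, Pdcd1, Havcr2 and Cd36 were too low to test between tissues and for the trend in pancreas.

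Pancreas against blood in KC mice (10 genes) gave 34 without the low-count filter, 487 with DESeq2, 65 without an age term, 42 with set in place of age, 37 in set 1, 5 in set 2 and 4 without the 4-week libraries. None of the 37 was among the 10, and 4 of the 5 were. With title numbers as a block it gave 14 genes, 9 of them shared. The age trend in KC pancreas (28) gave 686 without the filter, 735 with DESeq2, 18 on log2 age, 2 with the acinar covariate and 6 with other-cell genes removed. It gave 0 with set as a covariate, in set 1, in set 2, without 4 weeks and with Xist (624, 1246, 275, 541 and 933 at an unadjusted edgeR p under 0.05). The age trend in KC blood (0 by edgeR, 870 at an unadjusted p under 0.05) gave 102 without the filter, 412 with DESeq2 and 16 on log2 age. The difference of the trends (6) gave 0 with RLE, with the replicate block (499 at an unadjusted edgeR p under 0.05) and on log2 age, 1 with set and 343 with DESeq2. Beyond these, and the lists named in the report, the block changed no other call.

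KC against WT in pancreas (28) gave 175 with DESeq2 and 4 with the acinar covariate, and in blood (0) it gave 10 with DESeq2 and 5 with set as a covariate. Without the filter, 9, 13, 20 and 30 against 4 weeks (7, 26, 9 and 7) gave 25, 156, 56 and 27 genes. With DESeq2 they gave 231, 728, 777 and 623, and with the acinar covariate 1, 1, 1 and 2. At 13 weeks RLE gave 77, Xist 10 and set 1 alone 0 (1246 at an unadjusted edgeR p under 0.05), and at 30 weeks RLE gave 3. DESeq2 called 172 genes higher and 315 lower between tissues, 317 and 418 for the trend in pancreas, 170 and 242 in blood, 147 and 196 for their difference, and 123 and 52 for KC against WT in pancreas. Against 4 weeks it called 113 and 118, 367 and 361, 253 and 524, and 234 and 389 at 9, 13, 20 and 30 weeks. RLE moved the median of all genes by 0.10 between tissues, -0.11 for the trend in blood, 0.20 for KC against WT in blood, and 0.49, 0.10 and 0.11 at 13, 20 and 30 weeks. Of 58 list calls, camera with an estimated correlation gave 7 and fry 12. The 10 genes of the WT pair kept their signs with a prior count of 5.

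Leaving out 1 library gave 6 to 21 genes for pancreas against blood, 10 to 31 and 0 to 12 for the trends in pancreas and blood, and 0 to 13 for their difference. It gave 8 to 29 for KC against WT in pancreas and 0 to 2 in blood. Against 4 weeks it gave 1 to 18 at 9, 0 to 143 at 13, 1 to 30 at 20 and 1 to 27 at 30 weeks. Leaving out Sample_W1P8, Sample_W3P8 or Sample_W3B8 could not be estimated.

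Some directions turned. The ribosomal list between tissues had medians of -0.14 with set beside age and -0.66 in set 1, where the T cell core list (0.20) turned in its camera direction. Per 10 weeks, Igsf6 was -0.22 in pancreas without Sample_303P8 (up to 2.96 without another library) and the ribosomal list -0.46 without 4 weeks. In blood with set as a covariate the ribosomal list was 0.0045 and the acinar list 0.22. With the acinar covariate, immediate early genes in KC against WT pancreas were -0.13, and at 9 weeks proliferation genes were 1.32 and ductal genes 9.84. Acinar genes in KC against WT blood were 1.34 with set as a covariate. The cause was not tested.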

Other observations

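Every test of this part was planned or is a plain count.

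Metabolic genes fixed in advance did not pass between KC pancreas and KC blood. Genes of fatty acid synthesis, uptake and storage had a median of 0.04 (camera adjusted p = 0.231), cholesterol genes -0.32 (0.846), hypoxia response genes -0.76 (0.168) and glycolysis genes 0.27 (0.231). Genes of the unfolded protein response (0.18, adjusted p = 0.0922) and of the response to TGF-beta, a cytokine of residency and fibrosis (0.43, adjusted p = 0.0697), did not pass either. The cholesterol list had an upward camera direction beside its negative median.

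In the WT pair of 30 weeks, B cell genes had a median of -3.78 in pancreas over blood, erythroid genes -4.04 and platelet genes -4.95. Haemoglobin genes Hba-a1 and Hbb-bs were listed at 0 in each library.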
